A study of Mus musculus with 8 samples.

How the data were processed

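Chromatin accessibility was measured by ATAC-seq, in which a transposase cuts open chromatin and attaches sequencing adapters to the cut ends, in medullary thymic epithelial cells (mTEC) of C57BL/6 mice. These cells line the thymic medulla, where developing T cells are tested against self antigens. Per the labels, 4 populations were sorted from thymus digested with enzymes. mTEC-I was CD45 negative, Epcam positive, MHCII low and Itgb4 positive, mTEC-II was MHCII high, mTEC-III was Ly6D positive, and mTEC-IV was MHCII low, Itgb4 negative and L1cam positive. Each population had 2 libraries, and groups and replicate numbers were taken from the sample titles. Nothing in the labels says that the replicates came from separate animals, so p-values measure the spread between these libraries, which may be technical.

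Per the submitters' processing notes, bcl2fastq 2.15.0.4, Picard 1.108 and HOMER (version not given) were used with the mm9 mouse genome. The aligner, the removal of duplicate reads and any shift of read ends for the transposase are not given in the sources used here. Per the file headers, the authors called peaks in each library alone with HOMER findPeaks in factor style, with a fragment length of 300 bp, a false discovery rate of 0.001 and a signal 4-fold over the surrounding 10000 bp. Each peak in these lists carries the authors' normalized signal in tags per 10000000 and a findPeaks score, a tag count that was not scaled; the score was used only to rank peaks within a list. Per the file headers, the authors also merged the peaks of all libraries into a table of 74090 peaks with a median width of 159 bp, and gave for each library a signal in tags per 10000000 of its total tags together with the nearest transcription start site (TSS) and an annotation. The values of this deposited signal were whole multiples of 0.5 tags, that is of single read ends, for 100% of values in every library, within the rounding of the 2 decimals deposited. The read ends behind each value were thereby recovered.

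Because the merged table holds scaled values, limma-trend replaced the count test planned before the data were examined, as that plan provided for such values. Values were scaled by TMM factors and transformed to log2(value + 1). Features with at least 10 tags per 10000000 in at least 2 libraries were kept, a value filter that took the place of the planned count filter. limma 3.58.1 in R 4.3.3 fitted 1 coefficient per population over all 8 libraries. Each population was set against the mean of the other 3, and all 6 pairs were compared. A call against that mean can come from 1 of the 3 alone, so the pairs that were also called are given for gene counts and for some named genes. P-values were adjusted by Benjamini-Hochberg within each comparison, with a threshold of 0.05, and an adjusted p given without a tool's name is limma's. Fold changes are on the log2(value + 1) scale, which understates the change of features with low values. A peak was called specific to a population when it was higher than in each of the other 3. Peaks were also summed per gene over those that the authors' annotation assigned to the gene as its nearest and that lay within 10 kb of its TSS. A gene's value is accessibility near its TSS, not expression. The edgeR 4.0.16 quasi-likelihood test on the recovered read ends was added after seeing the data, and DESeq2 1.42.0 on the same read ends was chosen before the data were examined. Each tool had its own filter, so their counts rest on different sets. limma tested 58817 peaks and 15008 genes, edgeR 65091 and 15319, and DESeq2 74086 and 15694.

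Gene lists were fixed before the data were examined: tuft cells, bitter taste receptors, mature Aire-stage mTEC, MHC class II presentation, tissue-restricted antigens, basal keratin and adhesion, cornified epithelium, other lineage regulators, non-canonical NF-kB, interferon response, cell cycle, thymic epithelium, cortical TEC, thymocytes, myeloid and dendritic cells, B cells, mesenchyme, endothelium and housekeeping. They were tested with camera at a preset correlation of 0.01, adjusted over 19 lists in 4 comparisons, and again with an estimated correlation and with fry. Camera compares a list with all other genes tested. A few genes stand in more than 1 list, such as Relb, Traf1 and Cd40. The list named non-canonical NF-kB also holds genes of the canonical pathway, such as Nfkb1, Rel and Rela.

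The genes named in the text follow a rule fixed before the data were examined. For each population they are the genes of the sort (Itgb4, L1cam, Ly6d, H2-Aa, H2-Ab1, Epcam, Ptprc), 10 fixed regulators and keratins, and up to 4 genes per list that passed the threshold with the largest absolute change, where a list held at least 2. Added to these are the 8 genes with the largest rise and the 8 with the largest fall whose values in both libraries lay beyond all others and whose mean log2 CPM was at least 3, leaving out predicted genes, microRNAs, small nucleolar RNAs and symbols ending in Rik. The 3 peaks with the largest rise among the 200 with the smallest p were taken per population, and 3 genes in each direction per pair. The text names a part of the genes this rule picks, and which of them to name was chosen after their values were seen; some are not reported here, and no other gene took their place. Genes named outside this rule are marked as such. Transcript identifiers at named peaks were matched to symbols through a RefSeq table of another assembly, GRCm38, from which no coordinate was used; 8 of 8 matched.

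Peak lists were compared with bedtools 2.31.1, counting any overlap of 1 bp or more. Promoter peaks were those within 1 kb of a TSS, and their share was tested with a two-sided Fisher's exact test. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 was used for tables and plots.

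Libraries held 3606440 to 10374600 total tags, of which 433007 to 1691730 lay in merged peaks, and the median merged peak held 3.00 tags in the shallowest library and 13.0 in the deepest. A population with no tags in either library was given a floor of 3 tags per library, which covers counting error only. Replicates were compared by the chi-square of tags per peak over peaks with at least 20 tags. Counting noise alone gives 1 if both ends of every fragment fall in the same peak, and less if they do not. The chi-square was 1.02 in mTEC-I, 1.18 in mTEC-II, 1.12 in mTEC-III and 1.05 in mTEC-IV, so no library was counted as a copy of another. This does not tell separate animals from repeated libraries of the same cells.

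The fits were tested on simulated data with 200 changed features in each comparison. Each comparison was drawn once, with a dispersion of 0.03, read ends drawn singly and all other features equal in the 4 populations. Far more features were called in the data, such as 37.4% of peaks in mTEC-I, so the simulated shares need not hold there. Among genes changed 4-fold, limma recovered 97% for mTEC-I, 96% for mTEC-II, 98% for mTEC-III and 99% for mTEC-IV, against 91% for mTEC-II with mTEC-III. Among peaks changed 4-fold these shares were 78%, 84%, 79% and 76%, against 69% for mTEC-II with mTEC-III. Of changes of 2-fold limma recovered 14%, 20%, 32% and 17% of peaks and 58%, 55%, 61% and 63% of genes, against 13% and 34% for mTEC-II with mTEC-III (9% and 27% with edgeR). False calls among the simulated peaks made up 0% for mTEC-I, 5.45% for mTEC-II, 3.13% for mTEC-IV, 32.7% for mTEC-III and 9.89% for mTEC-II with mTEC-III. Among simulated genes they made up 16.8% for mTEC-III and 11.3% for mTEC-II with mTEC-III. With edgeR the false calls in mTEC-III made up 3.16% of peaks and 7.59% of genes, so edgeR's counts are given beside limma's for that population.

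Alternatives covered the scaling (size factors of DESeq2, total tags in peaks, TMM from promoter peaks, cyclic loess, and the authors' own scaling to total tags), the pseudocount, the minimum value, the test, the distance that assigns peaks to genes, the replicate number as a block, libraries thinned to equal depth and leaving out each library. Equal depth here means the same number of tags in merged peaks, while total tags were not matched. The value filter was applied anew when a library was left out, so peaks open in 1 population alone could go untested. Tested peaks numbered 58817 with all libraries and 51219 or 51352 without mTEC-I replicate 1 or 2. Without mTEC-IV replicate 1 or 2 they numbered 51352 or 52911, and 56461 to 58901 without a library of mTEC-II or mTEC-III. Falls in the calls of mTEC-I and mTEC-IV can thus come in part from the filter. Cyclic loess, the authors' scaling, robust limma, the larger pseudocount, the higher minimum, the removal of satellite and rRNA repeats and the thinning were chosen after seeing the data. A planned search for short sequence motifs was not run, because no mm9 sequence was used here.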

Results

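Accessible chromatin was profiled in 4 sorted populations of medullary thymic epithelial cells, named mTEC-I to mTEC-IV, with 2 libraries each. The question was how open chromatin differs between these populations, which were first told apart by their transcripts in single cells. mTEC-I libraries held 8574920 and 7033320 total tags, mTEC-II 3606440 and 6212180, mTEC-III 5131240 and 6537910, and mTEC-IV 6010020 and 10374600. The authors' own peak lists held 44288 and 39040 peaks for mTEC-I, 19008 and 27739 for mTEC-II, 10525 and 19507 for mTEC-III, and 30017 and 38108 for mTEC-IV. Of all tags, 19.7% and 19.7% lay in merged peaks in mTEC-I, 17.8% and 15.3% in mTEC-II, 8.44% and 11% in mTEC-III, and 18.1% and 14.2% in mTEC-IV. Of the 74090 merged peaks, 24.1% lay within 1 kb of a TSS, 37.6% were annotated as intronic and 37.3% as intergenic. Because mTEC-III held the lowest share of tags in peaks, the choice of scaling mattered. TMM set the median log2 difference of all genes near 0. With the authors' scaling to total tags that median was -0.85 in mTEC-III, 0.46 in mTEC-I, 0.21 in mTEC-II and 0.20 in mTEC-IV. The median over all peaks was then -0.72 in mTEC-III, 0.46 in mTEC-I and 0.20 in mTEC-II. TMM factors from promoter peaks put the median over all peaks at 0.12 in mTEC-III and -0.11 in mTEC-IV.

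By correlation mTEC-I and mTEC-IV stood farthest apart, and mTEC-II and mTEC-III lay closest. Across merged peaks, the log2 values of mTEC-I and mTEC-IV libraries correlated with a mean Pearson's r of 0.385 over 4 pairs of libraries, against 0.820 for mTEC-II with mTEC-III. Replicates correlated at 0.937 in mTEC-I, 0.874 in mTEC-II, 0.815 in mTEC-III and 0.925 in mTEC-IV, so mTEC-III libraries resembled mTEC-II libraries (0.795 to 0.846) about as closely as each other. The other pairs gave 0.682 for mTEC-I with mTEC-II, 0.635 for mTEC-I with mTEC-III, 0.603 for mTEC-II with mTEC-IV and 0.655 for mTEC-III with mTEC-IV. These correlations are across peaks, which are not independent replicates. The first principal component held 52.2% of the variance and ran from mTEC-I through mTEC-II and mTEC-III to mTEC-IV. Taking 10525 best-scored called peaks from each library, replicates shared 82.7% of peaks in mTEC-I, 76.2% in mTEC-II, 72.9% in mTEC-III and 80.2% in mTEC-IV, and mTEC-II libraries shared 72.9% of theirs with mTEC-III. By this overlap mTEC-I and mTEC-IV did not stand apart from the other pairs: mTEC-I libraries shared 65.8% with mTEC-IV and 66% with mTEC-III, and mTEC-IV libraries 67.6% with mTEC-I.

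**Figure D1:**
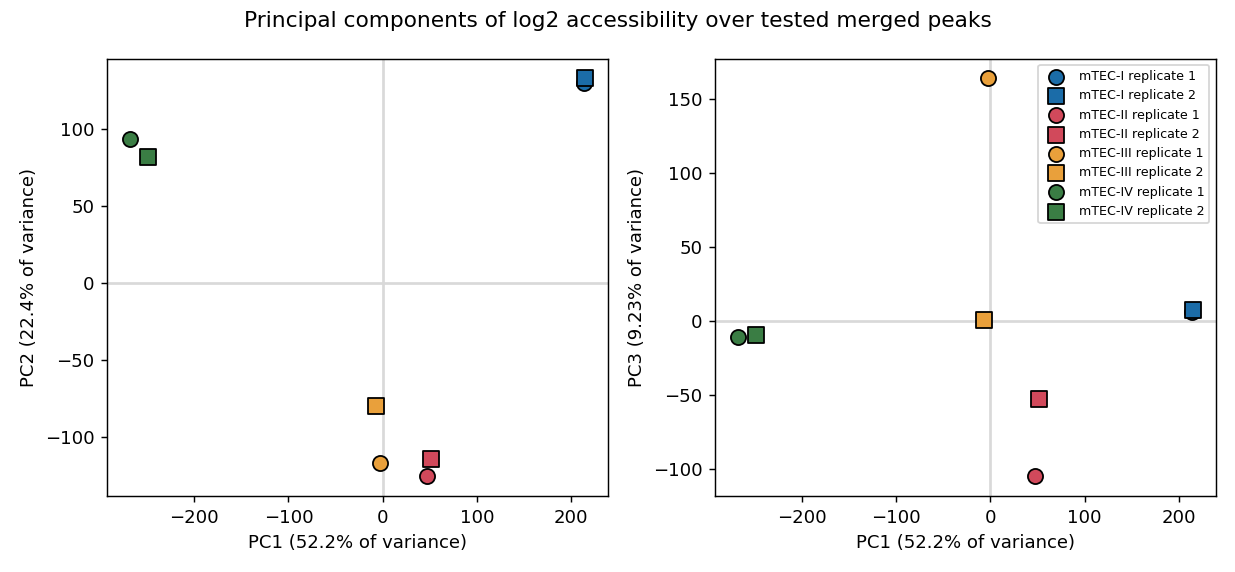
Principal components of log2 accessibility over the tested merged peaks, with component 1 (52.2% of variance) on the x axis of both panels and component 2 (22.4%) or component 3 (9.23%) on the y axis, in arbitrary units. Each point is a library, coloured by population, with replicate 1 as a circle and replicate 2 as a square; mTEC-I lies near 214 and mTEC-IV near -268 and -249 on component 1, and the mTEC-III replicates part on component 3 (164 and 0.598).

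L1cam, a cell adhesion molecule by which mTEC-IV was sorted, was most open there. It stood at 11.3 ± 0.891 TMM-scaled tags per 10000000 (SD, n = 2), below called normalized tags, and at 2.20 ± 0.763, 2.16 ± 1.46 and 3.34 ± 0.352 in mTEC-I, mTEC-II and mTEC-III. This was a rise of 1.83 ± 0.593 on the log2 scale (SE, limma adjusted p = 0.0365), though no single pair was called. The MHC class II genes H2-Aa and H2-Ab1 were most open in the MHCII-high mTEC-II (318.2 ± 15.3 and 297.8 ± 12.4) and in mTEC-III (299.3 ± 48.3 and 313.6 ± 58.4), and least open in mTEC-IV (154.1 ± 15.3 and 127.3 ± 3.37). H2-Aa was not called in mTEC-III (0.37 ± 0.108, adjusted p = 0.0558), and with the authors' scaling H2-Aa and H2-Ab1 stood at -0.50 and -0.29 there. Itgb4, an integrin chain of the basal cell surface, stood at 86.2 ± 13.7 in mTEC-I against 59.8 ± 11.2 in the other 6 libraries. This difference of 0.53 ± 0.198 did not pass the threshold with limma (adjusted p = 0.0578) but did with edgeR (adjusted p = 0.00934). Ly6d, the gene of the mTEC-III sort, stood at 63.3 ± 8.3 in mTEC-III against 43.8 ± 9.72 in the others, which did not pass with limma (0.55 ± 0.223, adjusted p = 0.166). Epcam, on which every gate was set, ranged from 141.1 ± 5.09 to 155.6 ± 5.5 with no call in any population, and Ptprc, which encodes CD45, had no merged peak within 10 kb of its TSS.

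**Figure D2:**
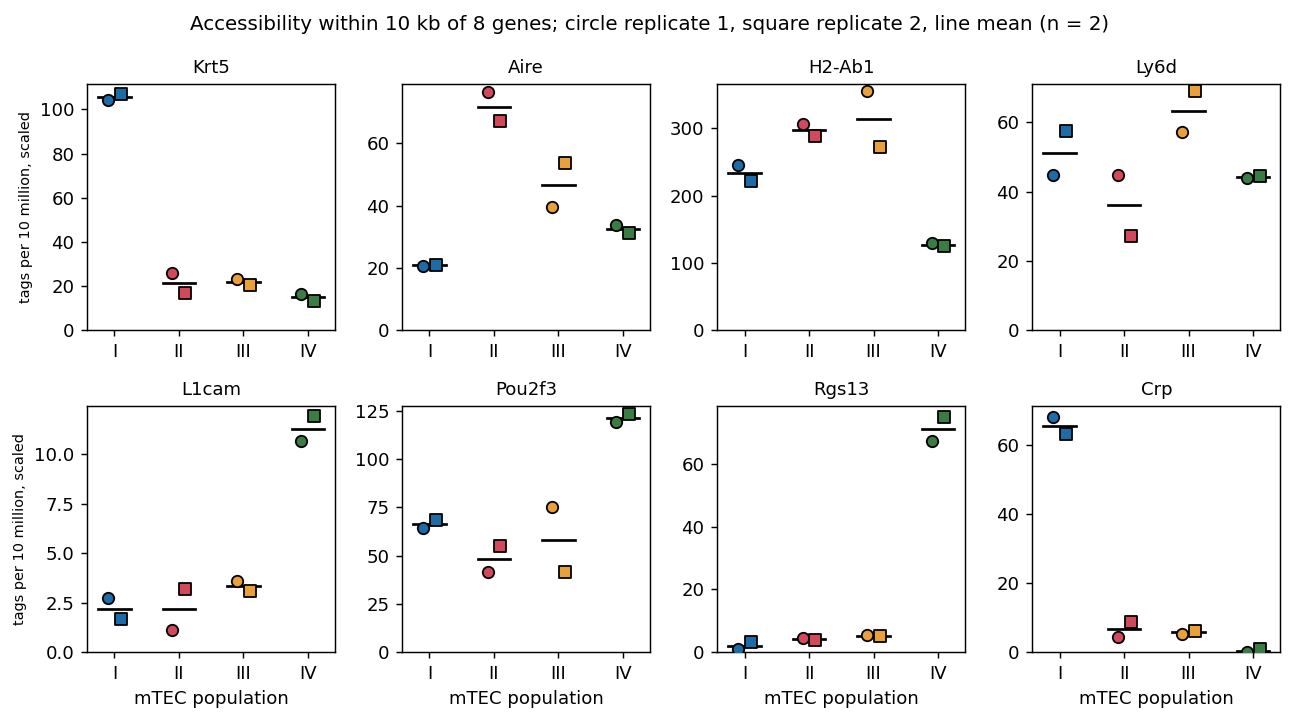
Accessibility summed over peaks within 10 kb of the TSS of 8 genes, in normalized tags on a linear y axis starting at 0, by mTEC population on the x axis. Circles are replicate 1, squares replicate 2 and lines the mean of 2 libraries; Krt5 and Crp stand highest in mTEC-I, Aire in mTEC-II, and L1cam, Pou2f3 and Rgs13 in mTEC-IV.

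In mTEC-I, chromatin was open near several genes of basal epithelium. Krt5, a keratin of basal epithelial cells, stood at 105.5 ± 2.08 normalized tags (SD, n = 2) against 19.4 ± 4.67 in the other 6 libraries, a rise of 2.42 ± 0.266 log2 (SE, adjusted p = 2.72e-06). Lamb3, a chain of the laminin that anchors basal cells, rose by 2.40 ± 0.309 and Pdpn, which encodes podoplanin, by 2.02 ± 0.373. Of 20 measured genes of the basal keratin and adhesion list, 9 rose and 2 fell, or 11 and 2 when adjusted over the list alone (camera, mean log2 0.54, adjusted p = 0.00303; adjusted p = 0.116 with an estimated correlation). Both that fell were tight-junction claudins, Cldn3 (-1.49 ± 0.164) and Cldn4 (-1.10), the latter named after its value was seen. Foxn1, the regulator on which thymic epithelium depends, rose by 0.88 ± 0.23 (adjusted p = 0.00825) and was called against mTEC-IV alone in pairs, while Trp63, a regulator of basal epithelium, was not called (0.41 ± 0.293, adjusted p = 0.35), though it passed the threshold with the authors' scaling (0.87). The cornified epithelium list was not called (mean log2 0.38, adjusted p = 0.111), with 4 of 22 genes higher and 1 lower, also when adjusted over the list alone, among them Spink5 (2.59 ± 0.478), a protease inhibitor of the epidermis, whose call was lost without mTEC-I replicate 2. Of 18 interferon response genes 5 rose and 2 fell, also when adjusted over the list alone, with Ifit3 at 2.43 ± 0.642, a call lost with libraries thinned to equal depth, and Ifit1 at -2.91 ± 0.573, a call lost without mTEC-I replicate 2 and over peaks at any distance.

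The largest rise in mTEC-I was at Crp, which encodes the C-reactive protein of the acute phase response (65.6 ± 3.4 against 4.30 ± 3.3, 4.01 ± 0.487 log2, adjusted p = 8.03e-06). Lingo4, Pdk4, a kinase that restrains pyruvate dehydrogenase, Slc46a2, a transporter of thymic stroma, Slc25a54, Fstl1, Mgp and Apoc1 rose by 2.81 to 3.34. Aire, the regulator of tissue-restricted antigens, fell by 1.16 ± 0.227 (adjusted p = 0.000974), and Cldn7, another claudin, by 3.01 ± 0.176 (adjusted p = 5.04e-10). Against a mean raised by mTEC-IV, genes of tuft cells, chemosensory epithelial cells, were less open: 18 of 30 fell and 1 rose (Dclk1, named after its value was seen), with the same numbers when adjusted over the list alone (camera, mean log2 -1.28, adjusted p = 2.56e-07; adjusted p = 0.0958 with an estimated correlation). The median of the list was 7.53 and 7.48 normalized tags in mTEC-I, 11.2 and 10.4 in mTEC-II, 12.6 and 14.5 in mTEC-III, and 54.9 and 52.3 in mTEC-IV. Alox5ap, which leukotriene synthesis needs, fell by 3.37 ± 0.424. Gnat3, the taste-cell G protein, had no tags in either mTEC-I library and was at least 5.15-fold lower than the mean of the others. That mean was carried by mTEC-IV (45.2 and 34.2), with Gnat3 at 3.37 and 1.60 in mTEC-II and 0 and 9.28 in mTEC-III. Of 12 measured bitter taste receptors, 9 fell against such a mean, also when adjusted over the list alone (mean log2 -1.86, adjusted p = 3.09e-05; adjusted p = 0.116 with an estimated correlation). Tas2r121, at 0 in both libraries, was at least 4.53-fold lower than a mean again carried by mTEC-IV (39.2 and 29.7, against 0 and 1.60 in mTEC-II and 10.8 and 1.02 in mTEC-III). Arhgef38, Pik3r6, Hc, Spn and the aldo-keto reductases Akr1c12, Akr1c13 and Akr1c19 fell, with log2 changes of -3.77 to -4.29.

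Some markers of cells that the gate should remove also moved in mTEC-I. The mesenchyme list rose, with 3 of 5 measured genes higher, also when adjusted over the list alone (camera, mean log2 0.93, adjusted p = 0.0149; adjusted p = 0.189 with an estimated correlation). They were Col1a1 (1.07 ± 0.177), Fbn1 (1.45 ± 0.407) and Tagln (0.87 ± 0.303). With libraries thinned to equal depth the list call was lost (0.68, adjusted p = 0.103). Of the endothelial genes, Emcn rose by 3.39 ± 0.691 and Sox18 by 1.46 ± 0.345, and Erg fell by 1.06 ± 0.272. Of T cell genes Lck fell (-3.12 ± 0.526) and Bcl11b rose (0.89 ± 0.156), and Cd79a of B cells (-2.52 ± 0.614) and Itgam (-2.74 ± 0.641), Cd68 (-2.49 ± 0.505) and Flt3 (-1.87 ± 0.36) of myeloid and dendritic cells fell, the last 2 not without mTEC-I replicate 1. Cd79a was called against mTEC-IV alone in pairs. Of 58817 tested peaks, 10623 were higher and 11375 lower in mTEC-I, and of 15008 tested genes 1749 were higher and 1547 lower; edgeR gave 15554 and 12127 peaks and 2447 and 2044 genes. Of the 1749 higher genes 819 were also called in the pair with mTEC-II, 1034 with mTEC-III, 1217 with mTEC-IV and 384 with all 3, and of the 1547 lower ones 804, 1016, 945 and 370. Leaving out mTEC-I replicate 1 or 2 left 1027 or 958 higher and 4002 or 3712 lower peaks, with 423 or 403 higher and 644 or 548 lower genes. Leaving out mTEC-IV replicate 1 or 2 left 6474 or 6697 lower peaks. The higher share of these calls, 48.3% of peaks and 53.1% of genes, was 72.6% (19564 and 7395 peaks) and 89.3% (4617 and 554 genes) with the authors' scaling and 59.4% of peaks (11489 and 7857) with cyclic loess.

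In mTEC-II, Aire and the genes of antigen presentation were more open than the mean of the other 3. Aire stood at 71.7 ± 6.57 normalized tags (SD, n = 2) against 33.3 ± 12.4 in the other 6 libraries, a rise of 1.16 ± 0.227 log2 (SE, adjusted p = 0.00646). Of 19 measured genes of the mature Aire-stage list, 6 rose and 0 fell, with 13 rising when adjusted over the list alone (camera, mean log2 0.74, adjusted p = 1.33e-09; adjusted p = 0.0749 with an estimated correlation). The costimulatory ligand Cd80 rose by 0.91 ± 0.243 and the checkpoint ligand Pdcd1lg2 by 0.86 ± 0.176. Cd80 was called against mTEC-I alone in pairs and Pdcd1lg2 against mTEC-IV alone, where it stood at 20.4 ± 2.2, and Pdcd1lg2 rose in mTEC-I too (0.93 ± 0.176). Of 13 MHC class II genes, 5 rose, or 10 when adjusted over the list alone (mean log2 0.47, adjusted p = 1.67e-07; adjusted p = 0.0958 with an estimated correlation), among them H2-Aa and H2-Ab1 (both 0.50) and H2-DMb2 (0.54 ± 0.102), each called against mTEC-IV alone in pairs.

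The non-canonical NF-kB list, which also holds genes of the canonical pathway, held 4 rising genes of 18 in mTEC-II, or 9 when adjusted over the list alone (mean log2 0.30, adjusted p = 6.65e-06; adjusted p = 0.076 with an estimated correlation). The 4 were Traf1, Traf6, Tnfrsf11a and Nfkbia, while Relb was not called. Tnfrsf11a, which encodes the receptor RANK, rose by 0.66 ± 0.14 and Traf6, its adaptor, by 0.76 ± 0.196, whereas Traf1 rose by 0.84 ± 0.164 over peaks within 10 kb and stood at -0.16 over peaks within 1 kb. Cornified epithelium genes were less open: 4 of 22 fell, or 7 when adjusted over the list alone (mean log2 -0.58, adjusted p = 6.11e-06; adjusted p = 0.076 with an estimated correlation). They were Calm4 (-2.22 ± 0.444), Calml3 (-1.33 ± 0.32), the desmosomal cadherin Dsc1 (-1.83 ± 0.458) and Grhl3 (-0.77 ± 0.184), a regulator of the skin barrier. Against a mean raised by mTEC-IV, tuft genes fell at 7 of 30, or 9 when adjusted over the list alone (mean log2 -0.69, adjusted p = 3.11e-05; adjusted p = 0.116 with an estimated correlation). The median of the list was 11.2 and 10.4 normalized tags in mTEC-II, 7.53 and 7.48 in mTEC-I, 12.6 and 14.5 in mTEC-III, and 54.9 and 52.3 in mTEC-IV, so the median in mTEC-II was not below that in mTEC-I. Of the bitter taste receptors 3 fell and Tas2r135 rose (2.07 ± 0.473), with 6 and 1 when adjusted over the list alone (mean log2 -0.82, adjusted p = 0.00303; adjusted p = 0.202 with an estimated correlation). Their median was 3.93 and 2.40 in mTEC-II, 1.60 and 0.554 in mTEC-I, 9.85 and 8.76 in mTEC-III and 36.2 and 31.2 in mTEC-IV. The myeloid and dendritic list rose (mean log2 0.60, adjusted p = 0.0157; adjusted p = 0.183 with an estimated correlation), with 1 gene of 9 higher, or 2 when adjusted over the list alone; the 1 gene was Zbtb46 of dendritic cells, named after its value was seen. That call was lost without mTEC-II replicate 2 (0.44, adjusted p = 0.192) or mTEC-III replicate 1 (0.49, adjusted p = 0.0509).

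The largest rise in mTEC-II was at Myo1g, a myosin of blood cells (67.9 ± 5.65 against 11.9 ± 12, 3.04 ± 0.407 log2, adjusted p = 0.000643), followed by Gprin2, Gdap1l1, Dlg2, Clca3b, Slamf6, Il1r2 and Kcnj3 with 2.19 to 2.76. Skor1, Wnk4, Il17re, Calm4, Gpld1, Tead2, Cacnb4 and Plxdc2 fell, with log2 changes of -1.90 to -2.67; edgeR did not call Cacnb4 (adjusted p = 0.0543). Over peaks at any distance Il1r2 stood at -0.07 and Skor1 at 0.11. In mTEC-II, 2940 peaks were higher and 2080 lower, and 353 genes were higher and 311 lower; edgeR gave 5225 and 1623 peaks and 633 and 307 genes. Of the 353 higher genes 285 were also called by limma in the pair with mTEC-IV, 251 with mTEC-I and 0 with mTEC-III, and of the 311 lower ones 230, 207 and 2. Leaving out mTEC-II replicate 1 or 2 left 0 or 97 higher and 1 or 702 lower peaks (limma, with 10438 or 12205 peaks at an unadjusted p under 0.05) and 18 or 50 higher and 29 or 189 lower genes. Leaving out mTEC-I replicate 1 or 2 left 1776 or 1614 higher and 859 or 780 lower peaks and 205 or 200 higher and 141 or 127 lower genes. Without mTEC-III replicate 1 or 2, 3257 or 3329 peaks and 479 or 546 genes were lower, and 551 genes were higher without its replicate 2. Without mTEC-IV replicate 1 or 2, 592 or 711 peaks and 107 or 126 genes were lower and 187 or 220 genes higher. The higher share, 58.6% of peaks and 53.2% of genes, was 70.4% (4560 and 1920 peaks) and 77.4% (401 and 117 genes) with the authors' scaling. With libraries thinned to equal depth limma called 0 peaks in either direction (11593 at an unadjusted p under 0.05) and 98 and 86 genes.

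In mTEC-III, genes of antigen presentation were again more open relative to all genes. H2-Ab1 stood at 313.6 ± 58.4 normalized tags (SD, n = 2) against 219.6 ± 77.6 in the other 6 libraries, a rise of 0.59 ± 0.111 log2 (SE, adjusted p = 0.00753) that became -0.29 with the authors' scaling. Of 13 MHC class II genes 3 rose (H2-Eb2, H2-Ab1 and H2-Eb1, the last at -0.55 with the authors' scaling), or 6 when adjusted over the list alone (camera, mean log2 0.33, adjusted p = 0.000383; adjusted p = 0.183 with an estimated correlation). Of the 19 Aire-stage genes Traf1 rose (0.77 ± 0.164, or -0.09 with the authors' scaling), or 2 when adjusted over the list alone (mean log2 0.42, adjusted p = 0.000383; adjusted p = 0.0958 with an estimated correlation). Aire itself was not called (0.32 ± 0.227, adjusted p = 0.446). Of 18 NF-kB genes Traf1 and Nfkbia (-0.54 with the authors' scaling) rose, or 6 when adjusted over the list alone (mean log2 0.22, adjusted p = 0.000862; adjusted p = 0.0966 with an estimated correlation). With the authors' scaling the means of the MHC class II, Aire-stage and NF-kB lists turned to -0.52, -0.51 and -0.64, below 0 but above the median of all genes.

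Dmkn, a dermokine of the upper epidermis, rose by 1.32 ± 0.343 and Ovol1, an epithelial regulator, by 0.75 ± 0.209 in mTEC-III (-0.11 for Ovol1 with the authors' scaling). Dmkn was called in no single pair and Ovol1 against mTEC-I alone. The cornified list as a whole was not called (mean log2 0.09, adjusted p = 0.679; 2 of 22 genes higher, or 4 higher and 1 lower when adjusted over the list alone). Krt14 rose by 0.65 ± 0.18 and Cldn3 by 0.74 ± 0.164, which became -0.22 and -0.12 with the authors' scaling. In pairs Krt14 was called against mTEC-IV alone (27.3 normalized tags there) and Cldn3 against mTEC-I alone (35.0 ± 2.31), and Krt14 rose in mTEC-I too (0.79 ± 0.18). The integrins Itga3 and Itga6 fell by 0.52 each, but edgeR called neither (adjusted p = 0.0599 and 0.0822), and Itga6 stood at 0.07 over peaks at any distance. Iapp, the islet amyloid peptide, rose (72.3 ± 22 against 33.6 ± 10.1) and S100a8 rose by 1.51 ± 0.427. The largest rises were at Bcl2a1d, a survival factor related to Bcl2 (42.7 ± 9.66 against 7.49 ± 5.42, 2.56 ± 0.415 log2, adjusted p = 0.00276), Ceacam18, Neu2, a sialidase, Hc, Clic3, Ly6g6c, Spn and Zp2, at 2.04 to 2.56.

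Of the 8 genes with the largest fall in mTEC-III (-2.21 to -2.79), Tgtp2, Wdr72, Scarf2 and Sox18 were also called by edgeR. Lrp3, Pdia5, Ppic and Mdga2 were not (adjusted p = 0.0593, 0.0803, 0.149 and 0.252 with edgeR). Over peaks at any distance Lrp3 and Mdga2 stood at 0.48 and 0.41. In mTEC-III, 1423 peaks were higher and 870 lower and 312 genes were higher and 287 lower; edgeR gave 3253 and 607 peaks and 395 and 148 genes. Of the 312 higher genes 265 were also called in the pair with mTEC-I, 205 with mTEC-IV and 3 with mTEC-II, and of the 287 lower ones 253, 164 and 1. Leaving out mTEC-III replicate 1 left 0 higher and 10 lower peaks (limma, with 10017 at an unadjusted p under 0.05) and 30 higher and 81 lower genes, and leaving out its replicate 2 left 3261 lower peaks and 822 lower genes. Without mTEC-I replicate 1 or 2, 607 or 622 peaks were higher and 137 or 130 lower, with 170 or 156 genes higher and 93 or 85 lower. Without mTEC-II replicate 1 or 2, 374 or 871 peaks were higher and 215 or 495 lower, and without its replicate 1, 188 genes were higher and 174 lower. Without mTEC-IV replicate 1 or 2, 214 or 259 peaks were lower, 140 or 179 genes higher and 97 or 108 lower, and 715 peaks were higher without its replicate 1. The higher share, 62.1% of peaks and 52.1% of genes, was 2.3% (431 and 18336 peaks) and 0.432% (48 and 11074 genes) with the authors' scaling and 75.9% of peaks (2209 and 703) with TMM from promoter peaks. With libraries thinned to equal depth limma called 1 peak in each direction (9267 at an unadjusted p under 0.05) and 69 and 66 genes.

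In mTEC-IV, genes of tuft cells were open. Rgs13, a regulator of G-protein signalling, stood at 71.0 ± 5.44 normalized tags (SD, n = 2) against 3.87 ± 1.63 in the other 6 libraries, a rise of 3.98 ± 0.466 log2 (SE, adjusted p = 4.34e-06). Gnat3 rose by 4.19 ± 0.727, Avil, the actin-binding advillin, by 3.76 ± 0.575, the taste receptor subunit Tas1r3 by 3.56 ± 0.598, and Pou2f3, the regulator that tuft cells need, by 1.10 ± 0.201 (121.2 ± 3.09 against 57.6 ± 14.2, adjusted p = 0.000515). Of 30 measured tuft genes 26 rose, or 28 when adjusted over the list alone (camera, mean log2 2.16, adjusted p = 8.38e-23; adjusted p = 0.0749 with an estimated correlation). Of 12 measured bitter taste receptors 10 rose and 1 fell (Tas2r135, named here after its value was seen), also when adjusted over the list alone (mean log2 2.56, adjusted p = 3.31e-08; adjusted p = 0.0847 with an estimated correlation), with Tas2r137 at 66.4 ± 0.0564 against 4.28 ± 4.85.

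**Figure D3:**
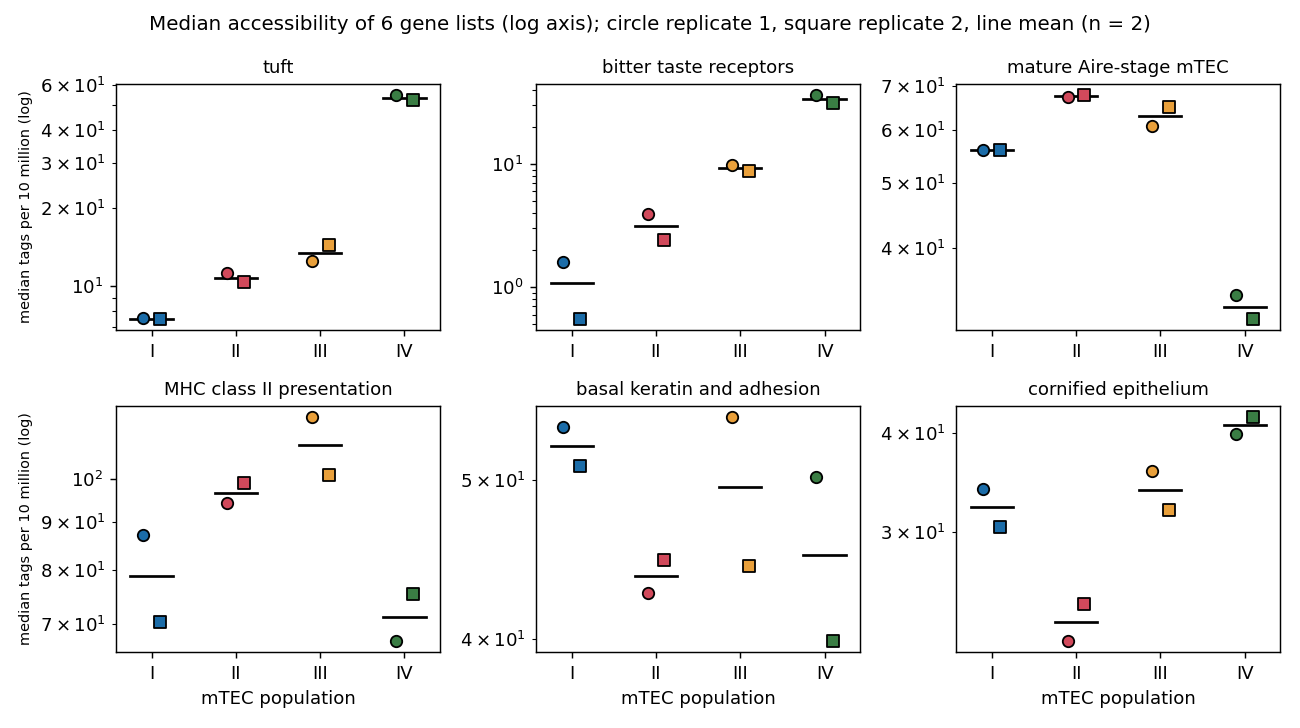
Median accessibility of the tested genes of 6 lists in normalized tags, on a log y axis that differs between panels and does not start at 0, by mTEC population on the x axis. Circles are replicate 1, squares replicate 2 and lines the mean of 2 libraries; the tuft and bitter taste receptor lists stand highest in mTEC-IV and the mature Aire-stage list lowest there, and with the authors' scaling the differences of mTEC-III in the Aire-stage and MHC class II lists change sign.

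Genes of antigen presentation were less open in mTEC-IV. Of 13 MHC class II genes 8 fell, also when adjusted over the list alone (mean log2 -0.65, adjusted p = 4.9e-07; adjusted p = 0.0966 with an estimated correlation), among them Ciita, their master regulator (-1.87 ± 0.262), and H2-Ab1 (-1.12 ± 0.111). Of 19 Aire-stage genes 11 fell, or 12 when adjusted over the list alone (mean log2 -0.79, adjusted p = 8.54e-07; adjusted p = 0.076 with an estimated correlation), led by Pdcd1lg2 (-2.19 ± 0.176) and the chemokine Cxcl10 (-1.61 ± 0.157), while Aire was not called (-0.33 ± 0.227, adjusted p = 0.384). Of 18 NF-kB genes 10 fell, or 14 when adjusted over the list alone (mean log2 -0.42, adjusted p = 8.54e-07; adjusted p = 0.076 with an estimated correlation), among them Cd40 (-1.08 ± 0.185). The keratins Krt14 (-1.85 ± 0.18) and Krt5 (-1.24 ± 0.266, called against mTEC-I alone in pairs) and the thymic regulator Foxn1 (-1.22 ± 0.23) fell, and Krt8 and Krt10 were not called (0.24 ± 0.123 and 0.14 ± 0.235).

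Of genes outside the fixed tuft list, Plac8, Cd300lf, the calcium-binding S100b, Rgs21, Dok3 and Agt, which encodes angiotensinogen, rose in mTEC-IV by 3.35 to 3.73. Absence from that list does not mean that tuft cells lack them. Il1r2, Gsdma3, Il16 and the olfactory receptor gene Olfr434 had no tags in either mTEC-IV library and were at least 5.14-fold, 5.13-fold, 4.50-fold and 7.56-fold lower than the mean of the others. Apoc1, Ntm, Primpol and Tnr fell, with log2 changes of -3.69 to -4.06. Some genes of lymphocytes, which the CD45 gate should remove, were open. Cd4 (19.7 ± 4.07 against 0.419 ± 0.684), Lck (2.71 ± 0.526 log2), Cd79a, Cd79b and Cd22 rose by 1.39 to 3.97, while Bcl11b of T cells fell by 0.61 ± 0.156; Cd22 and Bcl11b were called against mTEC-I alone in pairs. Neither the thymocyte list (mean log2 0.92, adjusted p = 0.341) nor the B cell list (0.93, adjusted p = 0.195) was called. In mTEC-IV, 10290 peaks were higher and 10828 lower and 1125 genes were higher and 1376 lower; edgeR gave 13575 and 11908 peaks and 1662 and 1665 genes. Of the 1125 higher genes 847 were also called in the pair with mTEC-I, 723 with mTEC-II, 481 with mTEC-III and 271 with all 3, and of the 1376 lower ones 1031, 843, 762 and 413. Leaving out mTEC-IV replicate 1 or 2 left 945 or 1596 higher and 4934 or 6337 lower peaks and 213 or 268 higher and 526 or 745 lower genes. Leaving out mTEC-I replicate 1 or 2 left 7120 or 7154 lower peaks. The higher share, 48.7% of peaks and 45% of genes, was 62% of genes (1195 and 733) with the authors' scaling and 38.3% of peaks (7767 and 12516) with cyclic loess.

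Between pairs of populations, few regions were called between mTEC-II and mTEC-III, where limma recovered 13% of simulated peaks and 34% of simulated genes changed 2-fold. Of 15008 genes limma called 4: Six2, a homeobox gene, was higher in mTEC-II (93.2 ± 14.3 against 40.8 ± 9.48 normalized tags, SD, n = 2; 1.18 ± 0.202 log2, adjusted p = 0.039), and Psapl1 (-2.01 ± 0.344, adjusted p = 0.039), Cdk3-ps (-1.40 ± 0.248, adjusted p = 0.0488) and Mir101c (-1.43 ± 0.21, adjusted p = 0.0129) were lower than in mTEC-III. Mir101c was named after its values were seen, edgeR did not call it (adjusted p = 0.444), and its mTEC-III libraries differed (2938 and 1397). edgeR called 2 genes higher and 13 lower and DESeq2 2 and 9, and 1844 genes had an unadjusted p under 0.05 with limma. Of 58817 peaks limma called 1 higher and 8 lower in mTEC-II, with 8184 at an unadjusted p under 0.05, against 37 and 248 with edgeR and 3 and 58 with DESeq2. Without mTEC-III replicate 2 the count was 1546, and 0 or 1 without any other library. The higher share, 11.1% of peaks and 25% of genes, was 96.5% (6550 and 240 peaks) and 99.5% (7633 and 40 genes) with the authors' scaling and 23% of peaks (17 and 57) with cyclic loess.

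The other pairs differed at far more peaks. limma called 11390 peaks between mTEC-I and mTEC-II, 13509 between mTEC-I and mTEC-III, 24432 between mTEC-I and mTEC-IV, 16374 between mTEC-II and mTEC-IV and 13814 between mTEC-III and mTEC-IV. Psapl1, Arsj and Lingo4 were higher in mTEC-I than in mTEC-II by 3.29 to 3.37 log2 and Myo1g, Gprin2 and Pik3r6 lower, at -4.16 to -4.94. Adamts20, Tgtp2 and Pdk4 were higher in mTEC-I than in mTEC-III by 3.32 to 4.08 and Hc, Neu2 and Spn lower, at -4.46 to -4.65. Crp and Apoc1 were higher in mTEC-I than in mTEC-IV by 5.56 ± 0.597 and 5.15 ± 0.509 and Alox5ap, Plac8 and S100b lower, at -4.93 to -4.97. Ntm was higher in mTEC-II than in mTEC-IV by 4.35 ± 0.455 and Rgs21, Cd300lf and Tas2r118 lower, at -4.05 to -4.23; Dnase2b, Scarf2 and Rgs13 were lower in mTEC-III than in mTEC-IV, at -3.52 to -3.98. Specific peaks numbered 2700 in mTEC-I, 0 in mTEC-II, 3 in mTEC-III and 4409 in mTEC-IV with limma, 4983, 6, 44 and 5493 with edgeR, and 2365, 0, 10 and 2856 with DESeq2; at an unadjusted p under 0.05 limma gave 409 in mTEC-II and 307 in mTEC-III.

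Without mTEC-I replicate 1 or 2, 2661 or 2563 peaks differed between mTEC-I and mTEC-II, 3186 or 3058 between mTEC-I and mTEC-III and 13238 or 13194 between mTEC-I and mTEC-IV, and 41 or 37 were specific to mTEC-I. Without mTEC-IV replicate 1 or 2, 11262 or 12982 peaks differed between mTEC-I and mTEC-IV, 4906 or 6391 between mTEC-II and mTEC-IV and 3416 or 4712 between mTEC-III and mTEC-IV. Then 67 or 107 peaks were specific to mTEC-IV and 1708 or 1780 to mTEC-I. Without mTEC-II replicate 1 or 2, 5261 or 7010 peaks differed between mTEC-I and mTEC-II, and 1351 were specific to mTEC-I without its replicate 1. Without mTEC-III replicate 2, 55 peaks were specific to mTEC-II and 55 to mTEC-III, and without any other library 0 were specific to mTEC-III. Peaks open in mTEC-I or mTEC-IV alone could fail the filter without 1 of its libraries, so these falls can come in part from the filter. The share of differing peaks that was higher in the first-named population also moved with the scaling. It was 49.1% for mTEC-I with mTEC-II, 46% for mTEC-I with mTEC-III, 50.6% for mTEC-I with mTEC-IV and 52.2% for mTEC-III with mTEC-IV, and 65.2%, 88.8%, 63.7% and 19.9% with the authors' scaling. With cyclic loess it was 58.1% for mTEC-I with mTEC-III, 65.7% for mTEC-III with mTEC-IV and 63.5%, against 49%, for mTEC-II with mTEC-IV, and with TMM from promoter peaks it was 66.3% for mTEC-III with mTEC-IV.

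Regions that rose or fell in a population lay at promoters less often than the other tested peaks, except those that fell in mTEC-III. Of the peaks higher in mTEC-I, 11.5% lay within 1 kb of a TSS against 30.8% of the other tested peaks, with 5.17% against 28.5% in mTEC-II, 5.13% against 27.9% in mTEC-III and 14.5% against 30.1% in mTEC-IV. Fisher's exact test, two-sided, gave odds ratios of 0.293, 0.137, 0.14 and 0.395 (adjusted p = 3.09e-222 in mTEC-II, 7.36e-107 in mTEC-III and 6.51e-251 in mTEC-IV, and below the smallest number the software holds in mTEC-I). Of the lower peaks, 11.8% lay at promoters against 31.1% of the others in mTEC-I, 13.3% against 27.8% in mTEC-II and 5.87% against 32.2% in mTEC-IV (odds ratios 0.298, 0.397 and 0.132; adjusted p = 2.72e-55 in mTEC-II, and below the smallest number the software holds in mTEC-I and mTEC-IV). Peaks lower in mTEC-III went the other way, with 40.3% at promoters against 27.1% (odds ratio 1.82, adjusted p = 7.32e-17). This share rests on 870 peaks called by limma, which made 32.7% false calls among simulated peaks in that comparison. edgeR called 607 lower peaks and DESeq2 203, and their share at promoters was not tested. The number of lower peaks also depended on which mTEC-III library was left out. Peaks lie beside each other and are not independent, so these p-values are too small.

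The peaks named here were picked by their rise only among those with the smallest p in each population. Other peaks may have risen more. Of the named peaks, the one with the largest rise in mTEC-I lay in intron 14 of 18 of Enox1 (mm9, chromosome 14, 78048385 to 78048539). It stood at 77.7 ± 0.503 normalized tags (SD, n = 2) against 3.78 ± 2.6 (4.23 ± 0.466 log2, adjusted p = 2.89e-05). In mTEC-II the named peak with the largest rise was intergenic on chromosome 17, 83566346 to 83566606, with Pkdcc as the nearest gene. It stood at 39.0 ± 1.9 against 5.18 ± 7.91 (3.83 ± 0.534, adjusted p = 0.00402). In mTEC-III the named peak with the largest rise lay in intron 9 of 12 of Tgm3, a transglutaminase of the cornified envelope (chromosome 2, 129865965 to 129866140). It stood at 35.7 ± 1.45 against 3.69 ± 2.84 (3.33 ± 0.502, adjusted p = 0.00876). Of the other named peaks, those of mTEC-I lay in an intron of Ddc and between genes near Rhbdl3, and those of mTEC-III in introns of Creb3l2 and Eya3. The 3 peaks named for mTEC-IV all lay in copies of large-subunit ribosomal RNA repeats. The first lay on chromosome 16, 11144129 to 11144285 (1035 ± 64.4 against 334.3 ± 47.6, 1.64 ± 0.132, adjusted p = 1.43e-06). Picked among the smallest p, these 3 need not be the peaks that rose most in mTEC-IV. Of 69 tested peaks in ribosomal RNA repeats 63 were higher in mTEC-IV, with a median log2 change of 1.37. How reads that match several copies were placed is not given, so these peaks may not be separate regions.

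The remaining lists were not called in any population, with the largest mean log2 change and its adjusted p (camera) as follows. Tissue-restricted antigens reached 0.36 in mTEC-III (adjusted p = 0.19), other lineage regulators 0.17 in mTEC-II (adjusted p = 0.34) and -0.18 in mTEC-IV (adjusted p = 0.247), interferon response genes 0.31 in mTEC-I (adjusted p = 0.203) and cell cycle genes 0.21 in mTEC-II (adjusted p = 0.0571). Thymic epithelium genes reached 0.10 in mTEC-IV (adjusted p = 0.306), cortical TEC genes 0.33 in mTEC-I (adjusted p = 0.173) and -0.31 in mTEC-IV (adjusted p = 0.0847), thymocyte genes 0.92 in mTEC-IV (adjusted p = 0.341) and B cell genes 0.93 in mTEC-IV (adjusted p = 0.195). Endothelial genes reached 0.50 in mTEC-I (adjusted p = 0.769) and housekeeping genes -0.12 in mTEC-I (adjusted p = 0.21). Within the housekeeping list Tbp (-0.79 ± 0.198), Eef2 (-0.44 ± 0.128) and Ywhaz (-0.34 ± 0.109) fell in mTEC-I, and with the authors' scaling Eef2 became 0.03 and Ywhaz 0.14. Gapdh, B2m and Actb fell in mTEC-IV, at -0.45 to -0.49, calls that were lost with the authors' scaling. Of the regulators fixed beforehand, Trp63 and Spib were not called in any population (-0.51 to 0.41 and -0.66 to 0.47), and Relb was called in mTEC-IV alone (-0.57 ± 0.109). With the authors' scaling Spib passed the threshold in mTEC-I (0.69) and mTEC-III (-1.51), and Relb in mTEC-III (-0.51) but no longer in mTEC-IV (-0.38). The mean and the median of a list differed in sign for thymic epithelium in mTEC-I (-0.03 and 0.27), cell cycle in mTEC-III (-0.08 and 0.10), interferon response in mTEC-II (-0.10 and 0.06) and tissue-restricted antigens in mTEC-IV (-0.34 and 0.01). It also differed for cell cycle in mTEC-I (0.00 and -0.03) and for thymocytes in mTEC-III (-0.02 and 0.20), and camera's direction was up for thymic epithelium in mTEC-I and thymocytes in mTEC-III and down for cell cycle in mTEC-I.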

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

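Replicate spread rested on 2 libraries per population, and where a library was left out, the lone library of its population was assumed to vary like the others. Features were then filtered anew, so peaks open in that population alone could go untested. The 6 correlations of replicate deviations between populations ranged from -0.014 to 0.0329. No pairing by replicate number was seen, though counting noise in these deviations could hide one. With the replicate number as a block 265 of 275 named gene results and 19 of 19 gene list calls kept their direction and side of the threshold. With the block Itgb4 in mTEC-I and H2-Aa in mTEC-III gained a call, and Krt14, S100a8, Itga6 and Mcm3 in mTEC-III, Tas1r3, Tas2r126 and Cdh1 in mTEC-II and Pax9 in mTEC-I lost theirs. Of 5905 alternative values for 275 named gene results, 5079 kept direction and side of the threshold, 708 lost the call, 35 gained one, 58 untested or uncalled ones moved and 25 changed sign. Of 247 alternative values for the 19 gene list calls, without fry and the estimated correlation, 241 kept both, 3 lost the call and 3 changed sign. With fewer tags peak calls were lost: thinned to equal depth, limma called 0 peaks in either direction in mTEC-II and 1 in each in mTEC-III. The thinning was drawn once, to the depth of mTEC-III replicate 1, which itself lost no tags. It cannot tell whether depth limited the calls at full depth. The search for sequence motifs was not run, since no mm9 sequence was used here. Alternatives chosen after seeing the data were edgeR, the authors' scaling, cyclic loess, robust limma, pseudocount 4, the minimum of 20 tags, the removal of repeats and the thinning. The cause of a change was not tested, except where fewer peaks, tags or libraries enter by construction (a higher minimum, a narrower window, a minimum fold, thinning, a left-out library).

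With the authors' scaling, peaks higher and lower numbered 19564 and 7395 in mTEC-I and 431 and 18336 in mTEC-III, and 4560 were higher in mTEC-II. Peaks differing between mTEC-I and mTEC-III numbered 29669 and between mTEC-II and mTEC-III 6790, and 6617, 264 and 0 were specific to mTEC-I, mTEC-II and mTEC-III. Genes higher and lower numbered 4617 and 554 in mTEC-I and 48 and 11074 in mTEC-III, with 117 lower in mTEC-II and 733 lower in mTEC-IV. In mTEC-III the list means became -0.51 for Aire-stage, -0.52 for MHC class II and -0.64 for NF-kB genes. Of named genes in mTEC-III, H2-Ab1 became -0.29, Foxn1 -0.76, Relb -0.51, Krt14 -0.22, Krt8 -0.64, Krt10 -0.76, H2-Eb1 -0.55, Cldn3 -0.12, Ovol1 -0.11, Traf1 -0.092 and Nfkbia -0.54. In mTEC-I, Rfx5 became 0.093, Eef2 0.03 and Ywhaz 0.14.

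With a minimum of 20 tags, 5492 peaks were higher and 6605 lower in mTEC-I, 1382 lower in mTEC-II, and 5656 higher and 6250 lower in mTEC-IV. Pairs then differed at 6815 (mTEC-I and mTEC-II), 8354 (mTEC-I and mTEC-III), 12827 (mTEC-I and mTEC-IV), 64 (mTEC-II and mTEC-III), 9686 (mTEC-II and mTEC-IV) and 8950 peaks (mTEC-III and mTEC-IV), and 1590, 8 and 2489 were specific to mTEC-I, mTEC-III and mTEC-IV. Thinned to equal depth, 0 peaks were higher and 0 lower in mTEC-II (limma, 11593 at an unadjusted p under 0.05), and 1 and 1 in mTEC-III. Pairs differed at 5774 (mTEC-I and mTEC-II), 6885 (mTEC-I and mTEC-III), 0 (mTEC-II and mTEC-III) and 7410 peaks (mTEC-III and mTEC-IV), and 788, 0 and 1983 were specific to mTEC-I, mTEC-III and mTEC-IV. Genes higher then numbered 1140 in mTEC-I, 98 in mTEC-II and 69 in mTEC-III, and lower 86 in mTEC-II and 66 in mTEC-III.

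edgeR called 5225 peaks higher in mTEC-II and 3253 in mTEC-III, 17184 between mTEC-I and mTEC-II and 285 between mTEC-II and mTEC-III, and 4983, 6 and 44 as specific to mTEC-I, mTEC-II and mTEC-III. By edgeR 633 genes were higher in mTEC-II and 148 lower in mTEC-III. DESeq2 called 668 peaks lower in mTEC-II and 203 in mTEC-III, 61 between mTEC-II and mTEC-III, 10 specific to mTEC-III and 2856 to mTEC-IV, and 158 genes lower in mTEC-II and 69 in mTEC-III. With pseudocount 4, 4321 peaks were lower in mTEC-II, 2435 higher and 2046 lower in mTEC-III, and 251 differed between mTEC-II and mTEC-III, with 5065, 22 and 45 specific to mTEC-I, mTEC-II and mTEC-III. TMM from promoter peaks gave 2209 peaks higher in mTEC-III. For peaks between mTEC-II and mTEC-III, and peaks specific to mTEC-III, the counts were 51 and 13 with TMM from promoter peaks, 0 and 0 with DESeq2 size factors, 50 and 10 with total tags in peaks, 49 and 8 with no filter, 67 and 8 with the replicate block, 58 and 10 with robust limma and 74 and 12 with cyclic loess. Cyclic loess gave 4 peaks specific to mTEC-II and 1544 to mTEC-IV, and a fit of only the 4 libraries compared gave 45 peaks between mTEC-II and mTEC-III.

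Over peaks within 1 kb, genes higher and lower numbered 844 and 699 in mTEC-I, 44 and 45 in mTEC-II, 95 and 125 in mTEC-III, and 273 and 435 in mTEC-IV. Traf1 in mTEC-II became -0.16 and Plcb2 in mTEC-III 0.37. Over peaks at any distance these counts were 3382 and 2765, 867 and 1009, 683 and 620, and 2442 and 2960. Tas2r118 in mTEC-I then became 0.34, Epcam -0.27, Il1r2 -0.075 and Skor1 0.11 in mTEC-II, Lrp3 0.48, Mdga2 0.41 and Itga6 0.07 in mTEC-III, and Epcam 0.47 and Dsc1 -0.88 in mTEC-IV. With an absolute log2 fold change of at least 1, genes higher and lower numbered 906 and 745, 181 and 157, 143 and 125, and 612 and 746. Of the 19 list calls, 0 passed with an estimated correlation (camera). Over all lists and populations 34 tests passed with fry, which asks whether a list moved and does not compare it with other genes.

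Leaving out each library in turn gave 958 to 11843 peaks higher and 3712 to 12456 lower in mTEC-I, 0 to 3648 and 1 to 3329 in mTEC-II, 0 to 1006 and 10 to 3261 in mTEC-III, and 945 to 11629 and 4934 to 11633 in mTEC-IV. Pairs differed at 2563 to 14097 (mTEC-I and mTEC-II), 3058 to 13722 (mTEC-I and mTEC-III), 11262 to 26642 (mTEC-I and mTEC-IV), 0 to 1546 (mTEC-II and mTEC-III), 4906 to 18524 (mTEC-II and mTEC-IV) and 3416 to 13744 peaks (mTEC-III and mTEC-IV). Specific peaks ranged over 37 to 2747, 0 to 55, 0 to 55 and 67 to 3805 in mTEC-I to mTEC-IV. Genes higher ranged over 403 to 2208, 18 to 551, 30 to 458 and 213 to 1498, and genes lower over 548 to 1909, 29 to 546, 81 to 822 and 526 to 1668. Gene list calls numbered 18 to 20. Without satellite and rRNA repeats, peaks higher in mTEC-III than the mean of the other 3 numbered 1516, and population-specific peaks, mTEC-IV, numbered 4052.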

Other observations

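The tests of depth and of a flatter profile, including its demand that both mTEC-II libraries decide alike, the gene families, the repeats and the list tests between mTEC-II and mTEC-III were chosen after the results were seen. Of 328 families of genes with a shared symbol, several moved together, with adjusted p over all families from camera; with an estimated correlation adjusted p = 0.992 for each. Serpina genes, protease inhibitors of the acute phase, rose in mTEC-I (mean log2 1.61, 7 of 9 higher and 1 lower, adjusted p = 0.000589) and fell in mTEC-IV (-1.44, 6 of 9, adjusted p = 1.91e-05). Collagen genes rose in mTEC-I (1.07, 12 of 23, adjusted p = 6.92e-05), as did the Ccl chemokines (1.25, 8 of 13, adjusted p = 0.0131). The mesenchyme list, which shares Col1a1 with the collagens, rose in mTEC-I as well (mean log2 0.93, adjusted p = 0.0149; adjusted p = 0.189 with an estimated correlation). Hoxc genes fell in mTEC-I (-1.77, 4 of 6, adjusted p = 0.00777). In mTEC-IV the Skint genes (-1.45, 7 of 9, adjusted p = 4.69e-05), the beta-defensin genes (-2.01, 5 of 6, adjusted p = 0.00255) and the interferon-induced Gbp genes (-0.79, 5 of 9, adjusted p = 0.0378) fell. These directions held with DESeq2 size factors, total tags in peaks, cyclic loess and the authors' scaling.

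Between mTEC-II and mTEC-III, 19 lists were tested, and 2 were lower in mTEC-II with camera. They were cornified epithelium (mean log2 -0.51, adjusted p = 0.000998; adjusted p = 0.214 with an estimated correlation) and bitter taste receptors (-0.70, adjusted p = 0.0249; adjusted p = 0.464 with an estimated correlation). Genes that edgeR called higher in mTEC-III, chosen after their values were seen, include Card14, a regulator of NF-kB in skin (adjusted p = 0.0146), and Dux (adjusted p = 0.00649), which limma did not call (adjusted p = 0.0706 and 0.0619). Of 51 tested peaks in satellite repeats, 25 were higher in mTEC-III, with a median log2 change of 0.94 that was 0.17 with the authors' scaling. They took 2.14% and 1.12% of peak tags in the mTEC-III libraries and 0.645% to 0.830% in the others. Ribosomal RNA repeats took 1.32% and 1.24% in mTEC-IV and 0.465% to 0.590% in the others. In both kinds of repeat the peaks may not be separate regions, since the placement of reads that match several copies is not given.

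Few peaks were called between mTEC-II and mTEC-III, where limma recovered 13% of simulated peaks changed 2-fold. With every library thinned to 433008 tags in peaks, the other 4 pairs with mTEC-II or mTEC-III still differed at 5774 or more peaks. mTEC-II and mTEC-III then differed at 0. Those 4 pairs differed at many more peaks at full depth, so they show only that large differences survive such depth. They cannot decide whether lower depth hid smaller differences between mTEC-II and mTEC-III. After subtracting replicate noise, the SD of the log2 differences was 0.419, or 0.353 ± 0.0054 of that between mTEC-I and mTEC-II. This SE comes from leaving out each chromosome in turn and does not cover the spread between libraries. By this measure mTEC-II and mTEC-III differed less than mTEC-I and mTEC-II. A wider spread between replicates may still have hidden differences: 8184 of 58817 peaks had an unadjusted p under 0.05 (limma). Replicates deviated most in mTEC-III (log2 SD 0.732, against 0.409 in mTEC-I). A shared identity of the populations and an overlap of their gates, since neither label excludes cells of the other, stay open and were not tested.

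By correlation, but not by overlap of equal numbers of peaks (mTEC-IV libraries shared 69.05% with mTEC-III and 69.2% with mTEC-II), mTEC-III lay nearer to mTEC-IV than mTEC-II did, and a flatter profile of its libraries cannot be told apart from a real shift. Against the mTEC-II library left out of the peak selection, mTEC-III was higher by a median log2 of 0.215 ± 0.0194 at mTEC-I peaks. At mTEC-IV peaks it was higher by 0.705 ± 0.00964. Both SEs come from leaving out each chromosome in turn and do not cover the spread between libraries. Replicates 1 and 2 of mTEC-II gave 0.343 and 0.087 at mTEC-I peaks and 0.75 and 0.66 at mTEC-IV peaks. Thus only replicate 2 argues against a flatter profile. Cells of mTEC-IV in the Ly6D+ gate, which does not exclude L1cam, may contribute. At 36 peaks of tuft genes mTEC-III lay 12% ± 1.85 of the way from mTEC-II to mTEC-IV. At 6690 other mTEC-IV peaks it lay 14.2% ± 0.291 of the way (both SE from redrawing peaks, without the spread between libraries). Its libraries did not agree on a constant share (9.83% against 14.5% and 14.1% against 13.8%), nor did the mTEC-II libraries left out of the selection (7.11% against 11.7% and 13.1% against 12.4%). A flatter profile would also give a constant share, the tuft regulator Pou2f3 stood at 48.3 ± 9.57, 58.3 ± 24.1 and 121.2 ± 3.09 normalized tags in mTEC-II, mTEC-III and mTEC-IV (SD, n = 2), and a biological likeness of mTEC-III to mTEC-IV stays open and was not tested.

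Promoters were over-represented among the 870 peaks that limma called lower in mTEC-III. In that comparison limma made 32.7% false calls among simulated peaks, and the calls of edgeR and DESeq2 were not tested for promoters. A low share of tags in peaks may contribute, since in 3 of 3 populations whose replicates differed in that share the replicate with the larger share had the higher promoter level relative to distal peaks (by 0.21, 0.11 and 0.09 log2 in mTEC-II, mTEC-III and mTEC-IV). A scaling that depends on peak height is argued against as the whole cause, since with cyclic loess 39.5% of the lower peaks lay at promoters against 27.1% of the others (odds ratio 1.75, 95% interval 1.54 to 1.995). A biological loss of promoter accessibility stays open and was not tested.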
